A study of Ovis aries with 4 samples.

How the data were processed

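Total RNA of 4 sheep conceptuses collected on day 14 of pregnancy was sequenced, 1 conceptus from each of 4 crossbred Columbia and Rambouillet ewes. A conceptus is the embryo with its extraembryonic membranes, which at this stage is an elongating filament made mostly of trophectoderm. Per the labels' protocols, conceptuses were recovered by flushing with 10 ml of buffered saline. Ribosomal RNA was then depleted with the RiboMinus system, per the labels' protocols. Strand-specific libraries were made from 20 ng of depleted RNA after 90 seconds of enzymatic fragmentation at 37 °C, per the same protocols. The libraries were pooled 3 to a chip and read on an Ion Proton with 440 flows, and bases were called with Torrent Suite 4.0.2, also per the labels' protocols. Which library shared a chip with which is not given in the sources used here.

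The values are RPKM, read counts scaled by transcript length and by library size, computed and deposited by the authors in a table of 25197 features. The unit is named in the deposited workbook only for the second table, whose 5527 features are those at 5 RPKM or more in all 4 libraries and whose values are identical to those of the larger table. The genome build was Oar_v3.1, per the submitters' processing notes. The aligner, the counting tool and the annotation release are not given in the sources used here, nor is whether the counting used the strand. The column sums ranged from 454387 to 522308 RPKM, so the values are neither CPM nor TPM. No read counts, gene lengths or library totals were used, so absolute depth is unknown and no counting interval can be given. For features above 0 in exactly 2 libraries, the most frequent ratio of their values was taken as the inverse ratio of depth. These ratios put the depth of conceptuses 2, 3 and 4 at 0.741, 1.030 and 0.660 of that of conceptus 1. Between 35.6% and 56.3% of the 71 to 163 features of a pair of libraries lay near that ratio, so these depths are rough.

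Symbols were taken from the table, where 15226 features have one, and 13412 of these symbols occur in the RefSeq gene table of the newer assembly ARS-UI_Ramb_v3.0, which was used for names only. A further 6935 features have an Ensembl identifier that the tables do not pair with a name, and 0 of these identifiers occur in the RefSeq table. Features of one name are numbered as copies (HSP70_1, HSP70_2), and reads of multicopy families can be shared between copies or lost. This bears on zeros: none of the 1012 U6, 300 5S ribosomal, 630 small nucleolar or 97 7SK RNA features had a value above 0 in any library, and RPL5, a ribosomal protein gene that every cell uses, was listed at 0 in all 4 conceptuses. A value of 0 is therefore reported as listed at 0 and not as absence of the transcript. Positions on the genome were not used. The deviation of each list in each library, described among the additional observations, was chosen after the data were examined.

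The 4 libraries form 1 group, and the design holds no second group to set against it. Before the data were examined, 28 gene lists with 852 genes, 20 gene pairs, the tests and the alternative settings were fixed. Of the 852 genes, 636 are in the table and the others were not analysed here. Named genes are the 20 with a symbol and the highest mean, both members of each pair, the 5 highest members of each list and any gene past the variance test; others are said to have been chosen after their values were seen. Some genes that this rule names are not reported here. Means are given with the SD over 4 conceptuses (n = 4).

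The level of a list is the median of its members' log2(RPKM + 1), placed as a percentile among 10000 random lists of the same size. The random lists were drawn from 15234 features, those with a symbol plus list members that are named only in the feature column. On simulated lists shifted by 3 on the log2 scale, 100 of 100 lay above percentile 97.5, against 2 of 100 unshifted lists. Genes are not replicates, so the percentile describes these libraries and is no test across animals.

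The spread between conceptuses was tested with limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), a pseudocount of 1, for the 9602 features with mean RPKM of at least 1. Each feature's residual variance was set against limma's robust trended prior by an upper-tail F test with Benjamini-Hochberg adjustment at 0.05. A count model had been planned first, and this test was the written fallback for tables without counts. It was tested on simulated data for the 9602 features with 4 libraries, with all shifted features in 1 run. Of features with 1 library shifted by 3 on the log2 scale 0 of 100 were called. Of those shifted by 5 it called 96 of 100, with 3 false calls. A lone shifted feature was not simulated. Gene pairs were compared within each library by a two-sided exact sign-flip permutation test. Correlations are across features, which are not independent replicates. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Alternatives covered the RPKM minimum, the pseudocount, the scaling, the prior, the background and each conceptus left out in turn.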

Results

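RNA from 4 sheep conceptuses of pregnancy day 14, each from a different ewe, was profiled by sequencing of ribosome-depleted total RNA. The series names no treatment or contrast, so the values are levels within 1 group and the spread between its 4 members. Counts behind the RPKM are unknown. The most frequent ratios between libraries, over features above 0 in only 2 of them, put the shallowest, conceptus 4, at 0.660 of the depth of conceptus 1. A mean of at least 5 RPKM was reached by 6374 of 25197 features, and 668 reached 100 RPKM. The libraries correlated across features with a Pearson r of 0.982 to 0.990 on the log2(RPKM + 1) scale, and features are not independent replicates. Among features with a mean of at least 5 RPKM, at most 0.157% of values were identical between any pair, so no library was a copy of another.

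Trophoblast protein-1 (TP-1), the feature for interferon tau, the signal by which the ruminant conceptus is recognised by the ewe, was the most abundant gene with a symbol at 20347 ± 7992 RPKM (SD, n = 4). KRT8, a keratin of simple epithelia, followed at 6211 ± 1418 RPKM. LAMR1, described as laminin receptor, is another name of the ribosomal protein gene RPSA. With it, ribosomal protein genes such as RPS18 (2070 ± 391 RPKM), RPL8, RPL7A, RPL19 and RPL11 made up much of the remaining top 20. Both front-end fatty acid desaturases were among them, FADS2 at 2132 ± 528 and FADS1 at 1804 ± 631 RPKM, as were the chaperones HSP90AB1 at 1935 ± 489 and CALR at 1887 ± 253 RPKM. The antioxidant enzymes PRDX5 at 1709 ± 358 and MGST1 at 1610 ± 354 RPKM and the redox-related FAM213A at 1648 ± 349 RPKM also ranked there. GAPDH was the steadiest of these genes by range, at 2662 ± 146 RPKM, with the highest library 1.13 times the lowest. COX1, the mitochondrial cytochrome c oxidase subunit 1, stood at 1829 ± 389 RPKM.

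The 10 highest features of each library held 20.2 ± 2.67% of its summed RPKM (SD, n = 4), from 16.9% in conceptus 1 to 22.9% in conceptus 3. TP-1 alone held between 2.81% and 6.30%. Of the 20 highest features by mean, 11 carry an Ensembl identifier that the tables do not pair with a symbol, among them the highest of all, ENSOARG00000005662, at 20713 ± 1784 RPKM. A feature described in the table as pregnancy-specific antigen, chosen after its values were seen, was at 2526 ± 608 RPKM.

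**Figure D1:**
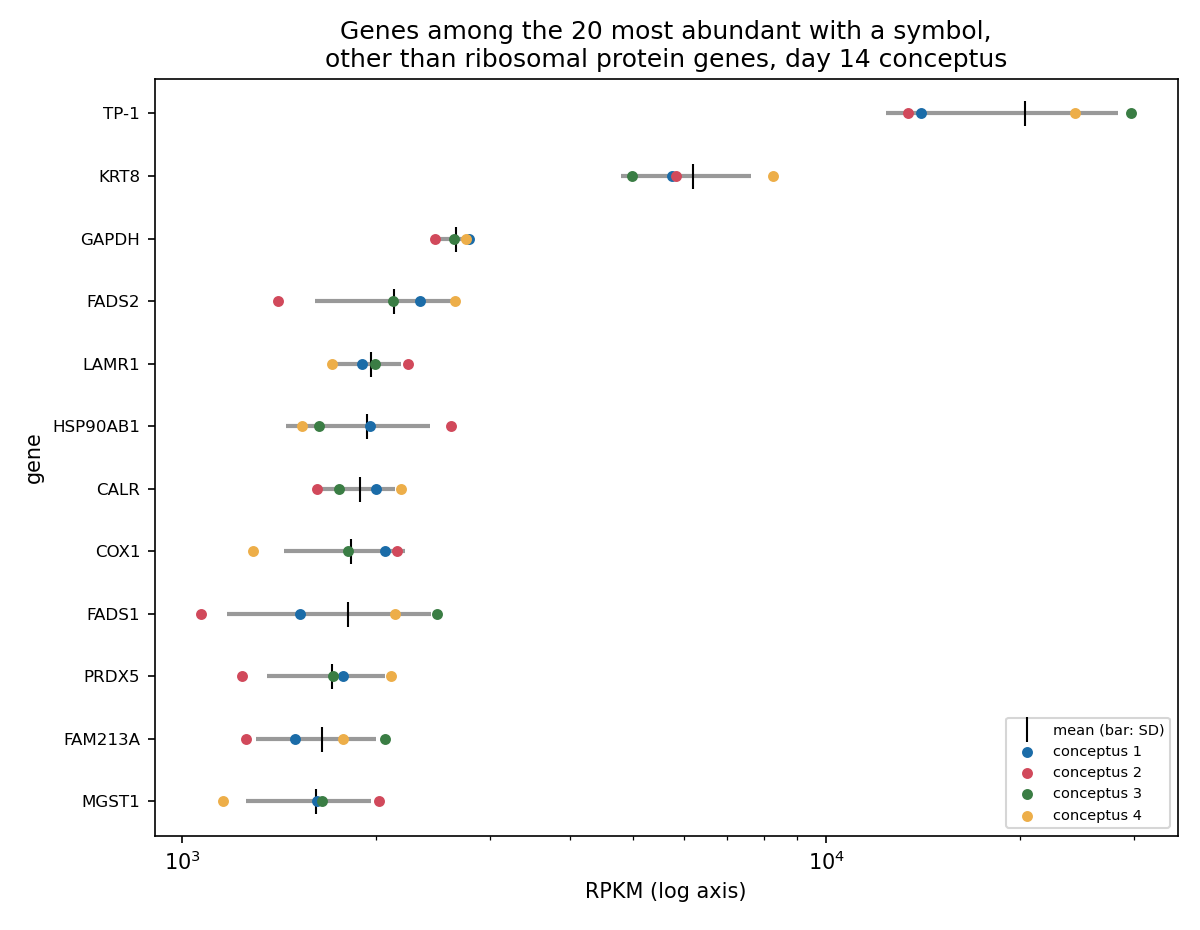
RPKM (log axis) of the genes among the 20 most abundant with a symbol, other than ribosomal protein genes named RPS or RPL. LAMR1, another name of the ribosomal protein gene RPSA, is therefore shown. Coloured points are the 4 conceptuses, the black tick is their mean and the grey bar is 1 SD to either side. TP-1, at 20347 RPKM, lies well to the right of KRT8 at 6211 RPKM, and the 4 GAPDH points lie close together.

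With all measured members counted, markers of trophectoderm had the highest list median among the cell type lists. Of the 27 measured trophectoderm regulators, 24 had a mean of at least 1 RPKM and 16 of at least 5, led by KRT8, the tight junction gene CLDN6 (181 ± 69.6 RPKM), the epithelial adhesion genes EPCAM (163 ± 30.3) and CDH1 (133 ± 13.3), and the epithelial transcription factor GRHL1 (86.9 ± 11.0). The lineage factors GATA3 and CDX2 stood at 29.3 ± 9.49 and 11.9 ± 3.90 RPKM. The list median lay at percentile 99.96 of random lists, and above percentile 97.5 in each of the 4 libraries. With only features of mean RPKM of at least 1 in list and background, called expressed features from here on, the percentile was 87.2, inside the central 2.5 to 97.5. The list of secreted trophoblast products then lay higher, at 97.2.

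Among genes of extraembryonic endoderm and yolk sac, 24 of 39 measured had a mean of at least 1 RPKM. The apolipoprotein gene APOA1 stood at 296 ± 105 RPKM, the endocytic adaptor DAB2 at 170 ± 24.05, the endocytic receptor LRP2 at 155 ± 38.1 and the retinol carrier RBP4 at 86.6 ± 24.6 RPKM, while the list median lay at percentile 69.3, and at 3.28 among expressed features. The epiblast and pluripotency list was uneven: 8 of 22 measured genes reached 1 RPKM. LIN28A stood at 202 ± 14.8, the DNA methyltransferase DNMT3B at 61.8 ± 5.66 and ZFP42 at 29.8 ± 3.94 RPKM, but the epiblast factor POU5F1 at only 2.08 ± 1.43 RPKM, and the list median lay at percentile 13.1 (27.0 among expressed features). Mesoderm and primitive streak genes were low, with 25 of 33 under 1 RPKM, VIM the highest at 10.8 ± 2.19 RPKM and the list at percentile 4.54. The mesoderm list lay below percentile 2.5 in 3 of the 4 libraries, and at 0.53 among expressed features.

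Blood, endothelial and leukocyte genes were close to the floor. In the blood and endothelium list 14 of 15 genes were under 1 RPKM, the exception being GATA1 at 2.67 ± 1.77 RPKM, and the list lay at percentile 7.995. In the leukocyte list 19 of 20 were under 1 RPKM, the exception being CD68 at 1.55 ± 0.417 RPKM, and the list lay at percentile 0.45, the only list below percentile 2.5, and at 0.03 to 0.66 without 1 conceptus. Genes used as markers of endometrium, the maternal tissue that surrounds the conceptus, gave a split picture. FXYD4, an ion transport regulator, and LGALS15, a galectin, stood at 214 ± 101.4 and 89.0 ± 6.87 RPKM, while 16 of the 20 measured members were under 1 RPKM, and the list lay at percentile 11.2. It lay at 68.4 among expressed features, where 4 members remain, and at 6.57 without conceptus 3. In single libraries the list lay lower, at 0.705 to 9.545, and below percentile 2.5 in 1 of them.

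**Figure D2:**
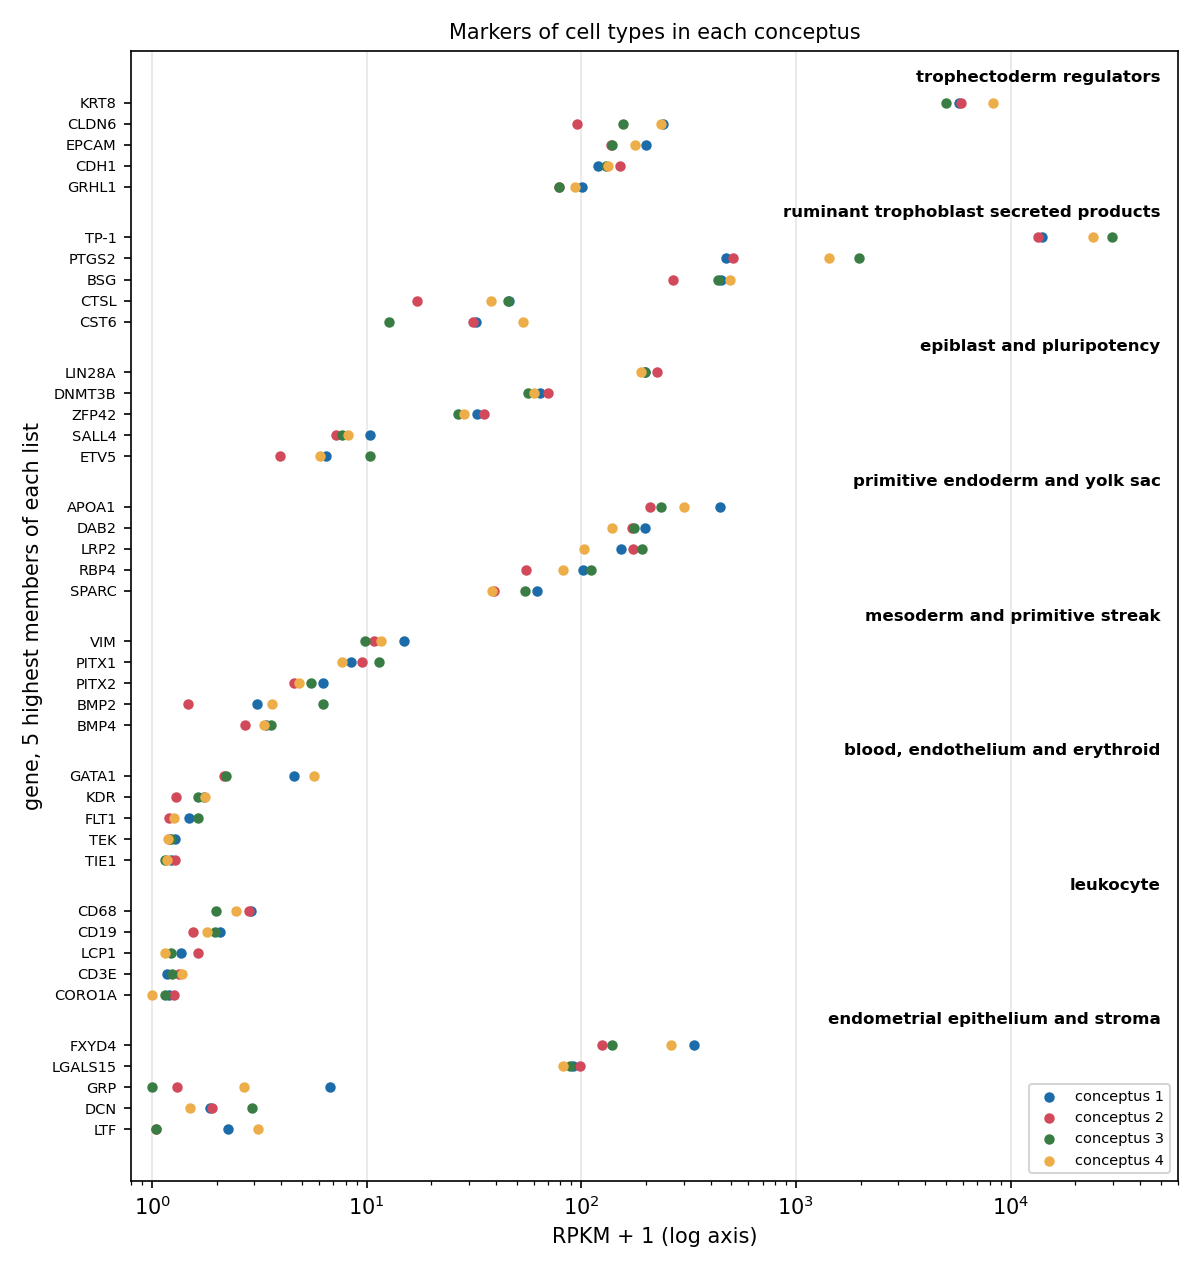
RPKM + 1 (log axis) of the 5 highest members of each cell type list, with 1 coloured point per conceptus. KRT8 and TP-1 lie furthest right, the leukocyte and blood genes lie near 1, and FXYD4 and LGALS15 stand apart from the other endometrial genes.

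The list of secreted and signalling products of the trophoblast, with 12 of its 36 genes measured, was led by TP-1, PTGS2 and BSG. The feature described as pregnancy-specific antigen, at 2526 ± 608 RPKM, was not among the measured members. PTGS2, the inducible cyclooxygenase of prostaglandin synthesis, stood at 1093 ± 731 RPKM, with 473, 507, 1968 and 1424 RPKM in conceptuses 1 to 4. BSG, a membrane glycoprotein, stood at 409 ± 98.4, the protease CTSL at 35.7 ± 13.5 and the protease inhibitor CST6 at 31.4 ± 16.7 RPKM. The list, with 12 measured genes, lay at percentile 90.7 (97.2 among expressed features).

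Within the prostaglandin list, few genes were high and most were near the floor: 13 of 22 measured genes were under 1 RPKM and the median lay at percentile 5.48. Besides PTGS2, the highest were the synthase and co-chaperone PTGES3 at 319 ± 60.5, the phospholipase PLA2G7 at 215 ± 48.4, the prostacyclin synthase PTGIS at 75.65 ± 25.98 and the prostaglandin E synthase PTGES at 67.1 ± 48.6 RPKM. Among expressed features, the remaining 9 members lay at percentile 99.94. PTGES was at 138 RPKM in conceptus 1 and its mean without that library was 43.5 RPKM.

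Interferon-stimulated genes were low beside the abundance of TP-1, with 21 of 29 measured members under 1 RPKM and a list median at percentile 9.86 (24.1 among expressed features). B2M, the light chain of class I antigens, was the highest at 392 ± 144 RPKM. IFI6 stood at 13.6 ± 6.42, EPSTI1 at 11.2 ± 7.05, STAT2 at 8.24 ± 0.688 and the antiviral GTPase gene MX1 at 5.22 ± 4.49 RPKM. MX1 was at 11.8 RPKM in conceptus 2, and its mean without that library was 3.04 RPKM. In the list of interferon receptors and signalling, the receptor subunit IFNGR1 stood at 6.24 ± 1.08 and the kinase JAK1 at 3.15 ± 0.438 RPKM, with the list at percentile 59.6, and at 12.2 among expressed features.

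Lipid metabolism was one of the best represented programmes. Of 59 measured genes, 38 had a mean of at least 5 RPKM and 10 of at least 100, and the median lay above all 10000 random lists in each library. After FADS2 and FADS1 came the elongase ELOVL5 at 958 ± 876, the acyl-CoA synthetase ACSL6 at 328 ± 43.7 and the glycerol-3-phosphate acyltransferase GPAM at 294 ± 22.3 RPKM. ELOVL5 ranged from 209 RPKM in conceptus 1 to 2090 RPKM in conceptus 3, and its mean without conceptus 3 was 581 RPKM. Among the 18 measured nuclear receptors and partners of the PPAR and RXR families, PPARD was the highest at 23.3 ± 5.02 RPKM. PPARG is outside the table, so PPARD was not ranked against it. The coactivators MED1 at 18.1 ± 3.17 and NCOA1 at 16.3 ± 3.85 RPKM followed. The list lay at percentile 82.9, but at 11.1 among expressed features.

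Glycolysis and pentose phosphate genes also lay above all random lists in each library, with 16 of 21 at 5 RPKM or more. PKM stood at 1044 ± 176, TPI1 at 443 ± 83.8, GPI at 330 ± 33.4 and the pentose phosphate enzyme TKT at 208 ± 26.3 RPKM. In the transporter list, at percentile 81.3 (71.5 among expressed features), the glucose transporter SLC2A3 stood at 311 ± 117, the monocarboxylate transporter SLC16A1 at 245 ± 52.2 and the glucose transporter SLC2A1 at 98.6 ± 26.8 RPKM. The arginine, nitric oxide and polyamine list lay at percentile 99.84. It was led by OAZ1 at 376 ± 181, ODC1, the rate-limiting enzyme of polyamine synthesis, at 252 ± 56.6, GCH1 at 179 ± 67.3 and SRM, the spermidine synthase, at 161 ± 21.05 RPKM. Steroid metabolism lay at percentile 48.4 (36.1 among expressed features), with the hydroxysteroid dehydrogenases HSD17B1 at 295 ± 110 and HSD17B12 at 193 ± 26.7 RPKM far above the other members.

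Cell division genes were present throughout: all 27 measured proliferation genes had a mean of at least 1 RPKM and 24 of at least 5, led by CCND2 at 336 ± 14.9, PCNA at 222 ± 31.3 and MCM7 at 162 ± 12.4 RPKM. The proliferation, translation and mitochondrially encoded lists each lay above all random lists in each library. The chaperones HSPA5 at 986 ± 130 and HSPA8 at 902 ± 97.3 RPKM headed the stress list after HSP90AB1, and that list lay at percentile 97.2, and above 97.5 without conceptus 1 (97.81), conceptus 2 (98.71) or conceptus 4 (98.455), but at 90.2 among expressed features. The tetraspanin CD9 at 1168 ± 141 and fibronectin, FN1, at 167 ± 35.1 RPKM headed the adhesion and matrix list, at percentile 93.3 (81.2 among expressed features). Growth factors and receptors lay at percentile 39.9, and at 4.59 among expressed features, with IGFBP1 at 28.9 ± 10.4, FST at 27.0 ± 3.64 and IGFBP3 at 26.2 ± 14.0 RPKM. The WNT list lay at percentile 39.1 (1.17 among expressed features) with WNT6 highest at 22.2 ± 11.98 RPKM, and the imprinted list at percentile 5 (7.65 among expressed features, 7.54 without conceptus 1 and 7.51 without conceptus 2) with NAP1L4 at 75.1 ± 12.2 and GNAS at 41.2 ± 7.45 RPKM. X- and Y-linked genes, led by RPS4X at 334 ± 17.5 RPKM, lay at percentile 94.3 (51.7 among expressed features), and histone genes, led by H2AFZ at 230 ± 31.9 RPKM, at percentile 84.0 (97.89 among expressed features). The list of abundant small noncoding RNA had 1 measured member, SCARNA7, listed at 0 in all 4 libraries. In total 7 of 27 lists lay above percentile 97.5 and 1 below percentile 2.5.

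**Figure D3:**
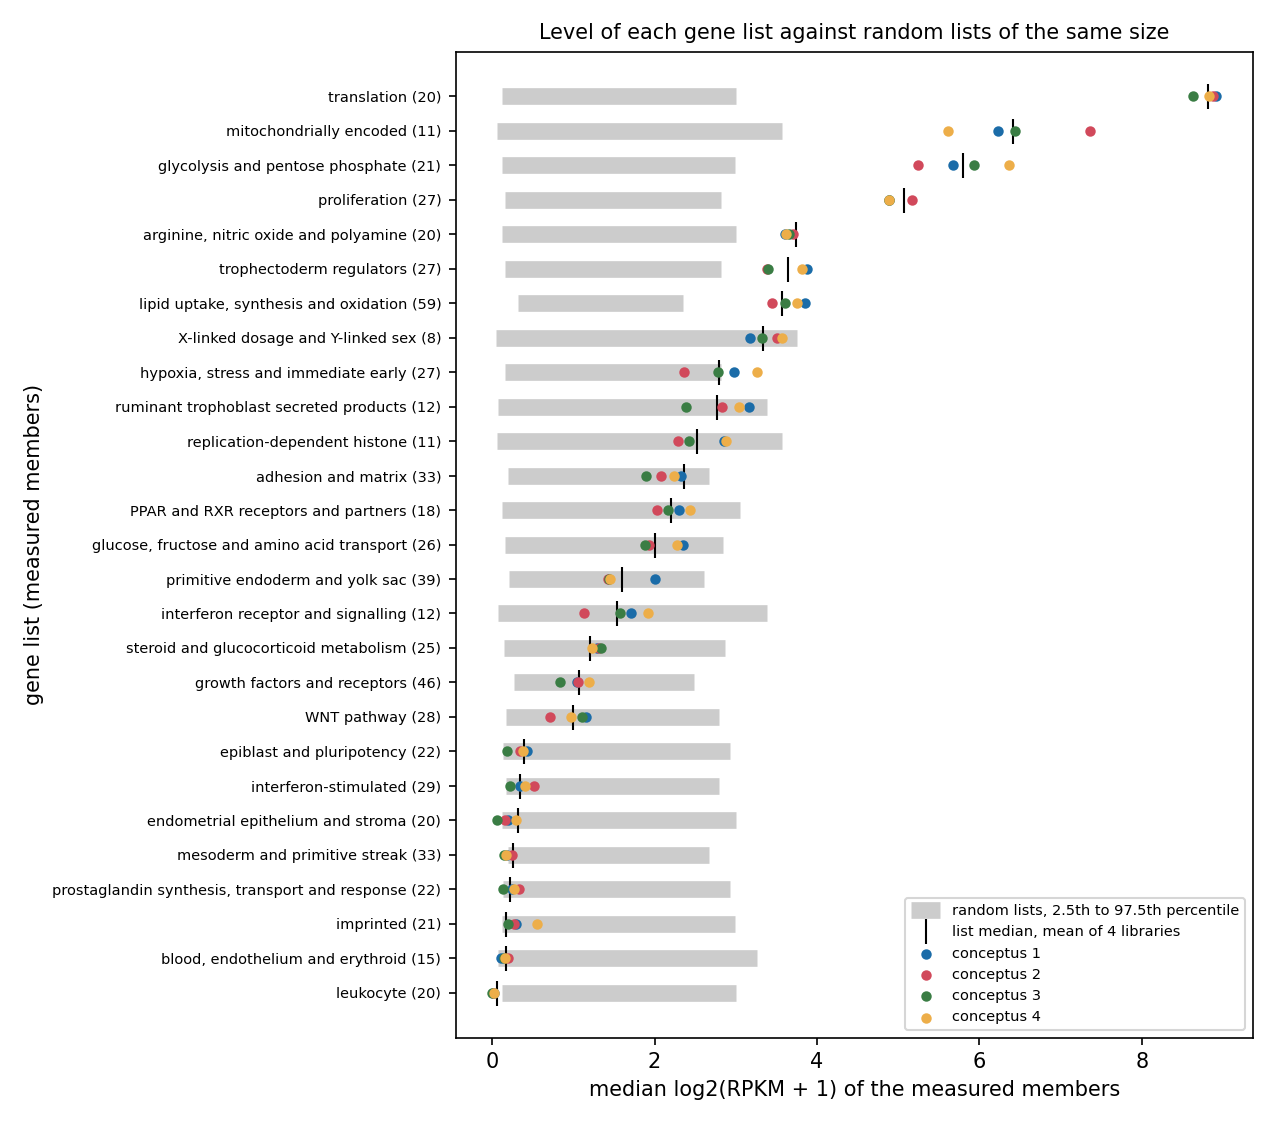
Median log2(RPKM + 1) of the measured members of each gene list (members in brackets). The black tick is the median of the members' means over the 4 libraries, coloured points are single conceptuses, and the grey bar spans the 2.5th to 97.5th percentile of 10000 random lists of the same size. The 7 lists from translation down to lipid metabolism lie to the right of the bar, and the leukocyte list lies to its left.

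Related genes were compared within each conceptus for 9 of the 20 fixed pairs. PTGS2 exceeded PTGS1, the constitutive cyclooxygenase, by 9.70 ± 1.08 on the log2(RPKM + 1) scale. PTGS1 was at 0.22 RPKM or less in each library and listed at 0 in conceptus 2, so the pseudocount sets the size of this ratio, which was 12.32 with a pseudocount of 0.1. LDHA exceeded LDHB by 4.16 ± 0.382. FABP5 was at 11.1 ± 2.49 RPKM and FABP4 was listed at 0 in all 4 conceptuses, so no direction is read from this pair. SLC2A3 exceeded SLC2A1 (log2 ratio of SLC2A1 over SLC2A3 −1.63 ± 0.652), GATA3 exceeded GATA2 by 2.35 ± 0.644, CDX2 exceeded POU5F1 by 2.13 ± 0.203 (2.62 with a pseudocount of 0.1), and FGFR2 exceeded FGFR1 by 1.76 ± 0.680. RXRB exceeded RXRA (log2 ratio of RXRA over RXRB −0.66 ± 0.228), and RXRA exceeded RXRG by 1.22 ± 0.401, or 2.45 with a pseudocount of 0.1. The 7 pairs with no value of 0 had the same direction in 4 of 4 conceptuses. The two-sided exact sign-flip permutation test gave p = 0.13 for each of the 9 pairs, values of 0 included, and 0.13 after adjustment over them, the smallest value that 4 conceptuses allow, so none can pass 0.05. Both members were under 1 RPKM in 3 more pairs (SLC7A1 and SLC7A2, IGF2 and IGF1, CYP19A1 and CYP17A1), and 8 pairs with a gene outside the table, among them both PPARG pairs, were not analysed here.

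The conceptuses resembled one another closely for most genes. Among the genes named by the fixed rule with a mean of at least 5 RPKM and no value of 0, the highest library was 27.8 times the lowest for MT-CO2, 9.99 times for ELOVL5 and 7.26 times for MX1. The median coefficient of variation of the 6374 features with mean RPKM of at least 5 was 20.5%, the highest library was over 2 times the lowest in 21.9% of them, and over 4 times in 2.35%. By limma's variance test 0 of 9602 features were called more variable than the trend, with 466 at an unadjusted p under 0.05 against 480.1 from chance. The trend and its prior were fitted to these same features, so a count near 480.1 follows largely from the fit. It does not measure whether the conceptuses differ. ELOVL5 had an adjusted p of 0.613 and MT-CO2 of 0.250 by limma. Without conceptus 1 the test called 11 features, without conceptus 3 it called 4 and without conceptus 4 it called 7. HSP70_2, named after its values were seen, was called in each of these 3 settings, and MT-CO2 without conceptus 1 or 4. In the simulation a shift of 3 on the log2 scale in 1 library was never called, so differences between animals of that size or smaller are beyond this test. The 100 features shifted by 3 and the 100 shifted by 5 were simulated together, which eases the adjustment for each. A lone difference can thus be missed at larger sizes. MT-CO2, 27.8 times as high in its highest library as in its lowest, was not called with 4 conceptuses.

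When adjusted over the list alone, the test called 4 genes in 2 of 25 lists: MT-CO2, MT-ATP8 and MT-ND6 among the 11 mitochondrial genes (the latter pair named after their values were seen), and the neuropeptide gene GRP among the 4 endometrial genes tested. The corresponding limma adjusted p values were 0.00201, 0.0463, 0.0463 and 0.0198, and over all features 0.25, 0.984, 0.984 and 0.971. Adjusting within a list was not part of the fixed plan and makes no correction over the 25 lists. MT-CO2 was at 32.6, 39.2, 906 and 39.2 RPKM in conceptuses 1 to 4, MT-ND6 at 38.3, 39.4, 19.7 and 9.48 RPKM, and GRP at 5.78, 0.3, 0 and 1.68 RPKM. MT-ATP8 was at 3.03, 4.08 and 2.11 RPKM in conceptuses 1 to 3 and listed at 0 in conceptus 4. With 0 calls over all features, the planned Fisher exact test of overlap between lists and calls was void. With the 466 features at an unadjusted p under 0.05 in place of calls, a setting chosen after the data were examined, 5 of 25 lists were overrepresented. These were the mitochondrially encoded genes (7 of 11, Fisher exact adjusted p = 4.22e-06), interferon-stimulated genes (5 of 8, 0.000163), and the trophectoderm (5 of 24), trophoblast secreted (3 of 9) and prostaglandin (3 of 9) lists, each with an adjusted p of 0.0383. The test treats genes as independent, which members of a list often are not.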

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

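In 191 sets of 4 values, the gap between the most extreme conceptus and its neighbour was set against the whole range, and 6 sets stood out; chance gives about 1 in 20, or 9.55 sets. SLC2A3 was at 487 RPKM in conceptus 3, against 250 to 255 RPKM in the others. MT-CO2 was at 906 RPKM in conceptus 3, against 32.6 to 39.2 RPKM in the others, and without that library its mean fell from 254 to 37.0 RPKM. The median of the primitive endoderm and yolk sac list was 3.02 RPKM in conceptus 1, with the next library at 1.74 RPKM. The median of the proliferation list was 35.1 RPKM in conceptus 2, with the next library at 28.6 RPKM. The log2 ratio of RXRA over RXRG was 1.81 in conceptus 1, with the next at 1.09, and that of LDHA over LDHB was 4.73 in conceptus 1, with the next at 4.03. No explanation was tested for these 6.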

How the results depend on the processing

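List percentiles depended most on the background. The number of features at the RPKM minimum moved from 6374 to 9602 with a minimum of 1, which is a looser limit by construction, and stayed within 1.5 times for all other settings. The lowest correlation was 0.982, and became 0.932 for features with mean RPKM of at least 5 and 0.978 with a pseudocount of 0.1; without 1 conceptus it was 0.982 to 0.985. The count of features more variable than the trend was 0 under all settings with 4 conceptuses, including a pseudocount of 0.1 chosen after seeing the data, and 0 to 11 without 1 conceptus; the cause was not tested. The 7 lists above percentile 97.5 stayed there with a pseudocount of 0.1 and without any 1 conceptus, and the stress list joined them without conceptus 1, 2 or 4. With the background limited to mean RPKM of at least 1, 6 of them did, and the prostaglandin and histone lists joined them at 99.94 and 97.89, since members under 1 RPKM then leave the list; trophectoderm fell to 87.2. With this background the endoderm, PPAR and RXR, and interferon receptor lists moved from above to below the middle (3.28, 11.1 and 12.2), and the prostaglandin and endometrial lists (68.4) from below to above it. The 9 pairs kept the sign of their log2 ratio in each setting, that of FABP5 over FABP4 resting on values of 0, and with a pseudocount of 0.1 the log2 ratios grew in size, 4 of them by more than the SD between conceptuses, that of PTGS2 over PTGS1 to 12.32. In the planned settings 0 lists passed the adjusted Fisher exact test of overlap with called features. Where there were 0 calls this test was void. The mitochondrial list held 1 called member without conceptus 1 and 1 without conceptus 4 (Fisher exact adjusted p of 0.315 and 0.201). With features at an unadjusted p under 0.05, chosen after seeing the data, 5 lists passed, since this replaces 0 calls by 466 features. Count models, a count-based filter, CPM and ratios of raw counts were not run, because the tables hold RPKM, and the share of reads was taken as a share of RPKM. Unknown depth leaves the precision of low values open.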

Other observations

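The tests in this part were chosen after the result was seen, except the comparison of numbered copies with other features, which the HSP70 and YWHAZ copies had prompted. Gene lists were also followed between conceptuses, as the median deviation of their members of mean RPKM of at least 1 from their own means, placed among 10000 random lists matched on mean expression. Mitochondrially encoded genes were the most uneven: their median deviation was 0.83 on the log2 scale in conceptus 2, with 10 of 11 members above the median of all features, and −0.80 in conceptus 4, with 0 of 11 above it, at percentiles 100 and 0. Interferon-stimulated genes lay at percentile 99.98 in conceptus 2 and 0.16 in conceptus 3. Genes of primitive endoderm and yolk sac lay at 99.83 in conceptus 1, 99.77 in conceptus 3 and 0.05 in conceptus 4, and lipid genes at 100 in conceptus 3 and 0.1 in conceptus 2. In all, 19 of 96 medians lay outside percentiles 2.5 to 97.5, where independent genes would give 5%; genes of a list are often regulated together, which the random lists do not carry.

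HSP70_1 was at 134, 65.2, 34.5 and 18.8 RPKM in conceptuses 1 to 4, and HSP70_2 at 0.8, 1.12, 47.9 and 128 RPKM. The sum of both copies differed by only 2.21 times between the highest and the lowest library, against 7.11 times for HSP70_1, but copies that run in opposite order always give a sum at least as flat as any other pairing of the libraries, so this does not decide whether reads of 1 gene were divided between them. Numbered copies in general reached an unadjusted variance p under 0.05 in 30.2% of cases (13 of 43) against 4.74% of other features, with a Fisher exact p of 6.74e-08. Without the copies of HSP70 and YWHAZ, 10 of 39 did (25.6%, Fisher exact p of 1.11e-05). The test treats copies as independent, which copies that share reads are not. Sharing of reads among copies is thus a candidate explanation for low variance p values of numbered copies, not shown for HSP70, and separate regulation of the copies was not tested. Most low p values, 453 against 13, belonged to other features.

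PTGS2, ELOVL5 and TP-1 were 4.16, 9.99 and 2.12 times as high in conceptus 3 as in conceptus 1. These genes were also high in conceptus 4, at 1424, 1206 and 24277 RPKM, against 507, 327 and 13397 RPKM in conceptus 2. The tables argue against scaling as the cause, since the log2 ratio of the median-of-ratios factors was −0.19, opposite in direction. Whether conceptus 3 held a larger share of trophectoderm is not decided. The 24 trophectoderm regulators had a median log2 ratio of −0.216 (SD of members 0.735), against 1.09 for TP-1, and 9 of them were higher in conceptus 3. They moved both ways, CDX2 from 17.2 to 7.89 and GATA3 from 29.7 to 40.4 RPKM between conceptuses 1 and 3. The list also holds genes of epithelia in general, so its median does not measure that share. A difference in stage or size of the conceptus is also possible, but the labels record neither and it was not tested.

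MX1, MX2, RSAD2 and IFI6 were 7.26, 21.3, 19.1 and 3.54 times as high in conceptus 2 as in conceptus 3. B2M, EPSTI1 and IFIT5 went the other way. MX2, RSAD2 and IFIT5 were named after their values were seen. Scaling between these libraries gave a log2 ratio of factors of 0.038, far below the median of 0.88 over the 8 members with mean RPKM of at least 1, of which 5 were higher in conceptus 2. Among the 21 members under 1 RPKM, near the floor, all but IRF9, HERC5 and GBP2 were higher in conceptus 2 than in conceptus 3. These exceptions were also named after their values were seen. RNA of the interferon-exposed endometrium carried with conceptus 2 could raise these genes, and its markers leave it open: the 4 with mean RPKM of at least 1 had a median log2 ratio of −0.002, too few to decide. Of markers near the floor, with a mean under 1 RPKM, MUC1, MUC16 and ESR1 were at 1.39, 0.96 and 0.65 RPKM in conceptus 2. In conceptus 3 they were at 0.12, 0.27 and 0.04 RPKM. CXCL14, STC1, OXTR and SERPINA14 were also higher in conceptus 2, while LUM (0.07 against 1.08 RPKM), PAX8 and HOXA10 were lower. All of these near-floor markers were named after their values were seen. No biological explanation was tested, since the design names no group within these 4 conceptuses.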
